A study of Agaricus bisporus with 8 samples.

How the data were processed

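The material was mycelium of the button mushroom Agaricus bisporus var. bisporus, strain H97, the strain whose genome serves as the reference for the species. Hyphae were placed on hay inside closed chambers and watered for 3 weeks with plain water or with water holding 50 µM riboflavin (vitamin B2). Watering was then stopped in the drought arm, and mycelium was taken on day 3 and on day 7. Per the labels, each of the 8 arrays carried drought RNA in one dye and RNA from mycelium that was still watered (irrigated) in the other. The 4 groups (water day 3, water day 7, riboflavin day 3, riboflavin day 7) held 2 arrays each. In replicate 1 of every group the drought RNA was labelled with Cy3, and in replicate 2 with Cy5, so replicate number and dye orientation are the same variable. RNA was labelled with Agilent's Low Input Quick Amp kit, per the labels. All 8 arrays lay on 1 slide.

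Per the file headers, the deposited scanner tables were made with Agilent Feature Extraction 11.5.1.1 and give spot and local background signals as a raw intensity in each of the 2 channels. The same deposited tables hold processed intensity values that Feature Extraction had background-subtracted and dye-normalized, and a log10 ratio of red over green, which was read only to settle the direction. A further table deposited by the authors holds log2 ratios of red over green. Limma is named in the submitters' processing notes, and every value of that table was reproduced to within 5e-10 by limma's normexp correction with an offset of 16 followed by loess. Its scale, its direction and its lack of centring between arrays are therefore known. Its column medians lay between -0.00308 and 0.00615.

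The median signals were corrected for local background with normexp and an offset of 50 and normalized within each array by loess, with control spots given a weight of 0, in limma 3.58.1 under R 4.3.3. Spots that the scanner software marked as outliers were left out (16 to 37 per array), and no gene spot was saturated. Each log2 ratio was turned to drought over irrigated. The 4795 probes with 2 spots were averaged, which left 10413 probes with 1 probe per gene. The array numbers its genes without naming them. These numbers matched a locus tag of the reference assembly Agabi_varbisH97_2 for 10348 probes and none for the other 65. Only 88 probes had a gene symbol in that table, which gives no descriptions. No build is named for the array design, so no coordinates are given.

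Probes were tested if they were well above background in at least 1 channel on both arrays of at least 1 group. This left 637 of the 10413 probes, of which 635 had a locus tag and 5 a symbol. Limma's lmFit and eBayes were fitted to all 8 arrays together, with 1 term per group and 1 for dye orientation. The residual degrees of freedom were 3, to which eBayes added 1.35. Contrasts gave the drought response of each group, the mean of the 4 groups, and the differences between supplements and between days. Irrigated mycelium with and without riboflavin was compared by limma's separate-channel fit of the 16 channels after loess and Aquantile normalization (intraspot correlation 0.138, 634 genes without missing values). P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Errors on fold changes are limma standard errors. They rest on 1 spread per gene over all 8 arrays, so opposed ratios in 1 group widen the errors and p-values of every comparison. Correlations were computed across genes, which are not independent replicates. Numbers given by chance at an unadjusted p under 0.05 likewise assume independent genes.

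The titles number the arrays of a group as separate replicates and the series design speaks of biological replicates, whereas the descriptions give both arrays of a group the same biological replicate number. P-values therefore measure only the spread between these arrays, which may be technical. An alternative fit that counts each pair of arrays as 1 value was run for that reason. For 3 groups, values argue against the same 2 RNAs with only the dyes swapped. In the irrigated channel of water day 3, 18 genes described below averaged 7.87 (replicate 1) and 11.44 (replicate 2) on the log2 scale. Their SDs were 0.58 and 1.04. Ratios of the riboflavin arrays as labelled correlated at -0.39 (day 3) and -0.49 (day 7). Whether the arrays came from separate cultures stays open.

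Genes named in the text were chosen by a rule fixed before the data were examined. Most of its parts needed descriptions of gene function, and it stated that without them only 1 part applies: the 2 largest positive and the 2 largest negative log2 changes of each comparison. The other genes go beyond that part and were chosen after their values were seen. They are the called gene, the 3 smallest p-values where nothing was called, the 5 tested genes with a symbol, genes alike in sign on several arrays, and genes called under an alternative. Of the 28 gene lists fixed beforehand, 1 (heat shock proteins and chaperones) had genes on the array, 5 in number, and none had a tested member, so no set test was run. The patterns of the others, among them riboflavin and flavin cofactor synthesis, antioxidant enzymes and compatible solutes, matched no gene symbol, and there were no descriptions to match. Symbols of the respiratory chain and ATP synthase (55 genes, 4 tested), of laccases and manganese peroxidases (7) and of osmosensing and histidine kinases (6) were grouped after the data were seen. Where a channel was not well above background on any array of a group, the ratio is given as a lower bound, taken from channel values after loess and Aquantile. It is a bound on the mean of the 2 arrays, so a single array can lie below it, and it leaves out the error. For differences between groups no bound was computed. None is given either where the other channel was near background on some of the arrays, and the genes concerned are named as such.

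The fits were tested on simulated data that had the residual spread of each real gene and 20 changed genes among 637. Simulated errors were independent between arrays and genes. The real replicate deviations correlated at 0.92 between the riboflavin days, so shares for comparisons that use riboflavin arrays may be too favourable. For the water day 3 drought response, 40.0% of 2-fold, 74.3% of 4-fold and 80.0% of 8-fold changes were recovered. For the mean over the 4 groups these shares were 75.7%, 87.1% and 90.8%. For the riboflavin difference averaged over days they were 41.4%, 75.7% and 80.8%. Of the simulated calls, 6.57%, 7.42% and 8.42% were false. With 200 changed genes, 2-fold changes were recovered for 69.8%, 86.8% and 69.8%, 4-fold changes for 85.0%, 95.2% and 85.4%, and 8-fold changes for 91.3%, 98.0% and 90.6%. For irrigated mycelium on day 3, with 200 changed genes among 634, the shares were 73.1%, 89.3% and 95.9%. The alternatives covered background correction, normalization, the filter on dim probes, the dye term, the variance model, single arrays left out, averaged dye pairs, each supplement fitted alone and the deposited log2 ratios. A turn of the direction of both riboflavin replicate 2 arrays (for irrigated mycelium, an exchange of their channels), their omission, and a random block were added after the data were seen. The number of arrays and the low signal limit the precision.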

Results

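The drought response of A. bisporus mycelium, and its dependence on vitamin B2 supplied in the irrigation water, was measured on 8 2-colour arrays. Signals were low on all of them. Between 478 and 797 of the 10413 probes (4.59% to 7.65%) were well above background in either channel of an array, and 8542 probes were not above it in any. The 3 brightest genes, AGABI2DRAFT_75870, AGABI2DRAFT_75612 and AGABI2DRAFT_187811, took 50.4% to 88.9% of the summed net signal of a channel. The log2 ratios of AGABI2DRAFT_75870 and AGABI2DRAFT_75612 differed by at most 0.03 on any array, so whether their probes read separate transcripts is uncertain. Duplicate spots of bright probes had log2 ratios that correlated at 0.940 to 0.990 within an array (120 probes).

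The ratios of the 2 arrays of a group correlated positively in water-grown mycelium and negatively in riboflavin-grown mycelium. Across the 637 genes, the log2 drought-over-irrigated ratios of replicate 1 and replicate 2 correlated at 0.37 on day 3 and 0.56 on day 7 with water. With riboflavin the correlation was -0.39 on day 3 and -0.49 on day 7. By ranks (Spearman's rho) these values were, in the same order, 0.33, 0.24, -0.24 and -0.31. Of the genes with a log2 ratio beyond 0.5 in size on both arrays, 3 of 34 (water, day 3) and 5 of 48 (water, day 7) had opposite signs. The corresponding counts with riboflavin were 47 of 71 on day 3 and 56 of 65 on day 7. The water counts include a set of 18 genes that varied together, described below. All 18 were among the 31 genes below -0.5 on both water day 7 arrays, where their highest ratio was -0.945. On water day 3, at least 15 were among 22 such genes. The agreement of the water arrays thus rests in part on 1 set. The replicate 1 riboflavin arrays of the 2 days correlated at 0.68 with each other, and the replicate 2 arrays at 0.88. Ratios of the riboflavin replicate 1 arrays correlated with those of the water arrays at 0.09 to 0.56, and those of replicate 2 at -0.32 to 0.02 (Spearman's rho -0.21 to 0.14, positive in 4 of 8 pairs). The dyes are stated in the labels, so the stated direction was kept. A mean over the riboflavin arrays of a day therefore averages opposed values for many genes. Values with the direction of both riboflavin replicate 2 arrays turned are given beside the larger changes, as an alternative chosen after the data were seen.

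**Figure D1:**
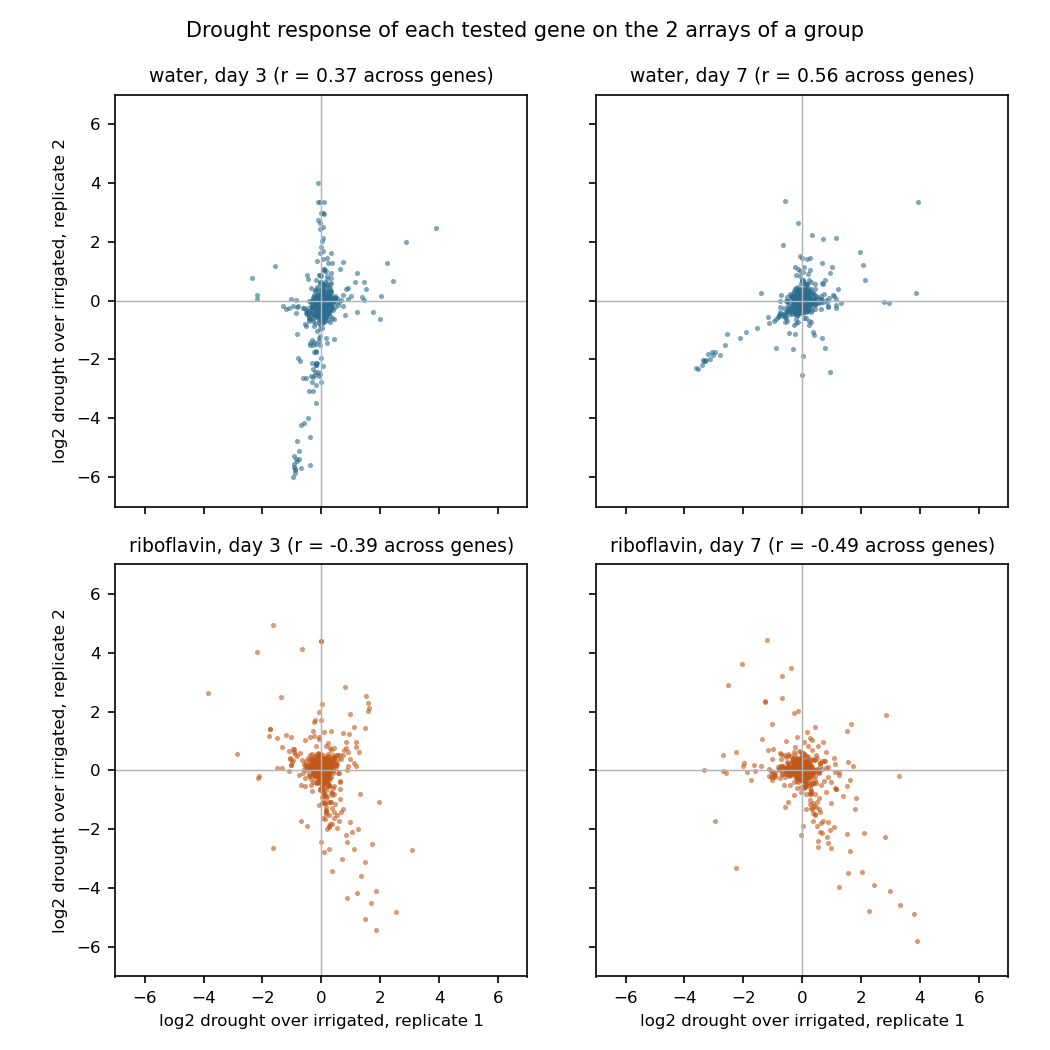
Each point is 1 of 637 tested genes; axes give the log2 drought-over-irrigated ratio on the replicate 1 array (horizontal) and the replicate 2 array (vertical) of the group named above each panel. The water groups lie along the rising diagonal (r = 0.37 and 0.56 across genes) and the riboflavin groups along the falling one (r = -0.39 and -0.49).

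After 3 days without irrigation, the largest negative log2 changes in water-grown mycelium belonged to genes of a set of 18 that varied together across the arrays (a set chosen after its values were seen, without symbols). AGABI2DRAFT_121746 had a log2 change of -3.49 ± 1.24 (SE, 2 arrays) and AGABI2DRAFT_146400 one of -3.37 ± 1.23, with an adjusted p of 0.390 for each. The drought channel of AGABI2DRAFT_146400 was not well above background on replicate 2, where its ratio was -5.84 (-0.89 on replicate 1), so its size and place are not exact. The size differed strongly between arrays, since AGABI2DRAFT_121746 had a log2 ratio of -0.97 on replicate 1 and -6.00 on replicate 2. The largest positive values belonged to AGABI2DRAFT_136259 (3.18 ± 1.79, adjusted p 0.533) and AGABI2DRAFT_191238 (2.43 ± 1.36, adjusted p 0.529). Their errors include opposed ratios on the riboflavin arrays, while their ratios on the 4 water arrays had an SD of 0.69 and 0.71. The smallest p-values belonged to AGABI2DRAFT_120986, with a log2 change of 0.85 ± 0.13, and to AGABI2DRAFT_151612 and AGABI2DRAFT_200290. The drought channel was not well above background on either array for AGABI2DRAFT_151612 and AGABI2DRAFT_200290. In the mean of the 2 arrays their irrigated signal was at least 1.96-fold and at least 2.41-fold higher. No gene was called by limma, whereas 75 of 637 had an unadjusted p under 0.05 (15 higher and 60 lower under drought) where chance gives 31.9. That number assumes genes that vary independently, whereas the set of 18 varied together, so it is no test of the excess. The count of 75 also changed widely between the alternatives. Without water day 3 replicate 1, 93 genes were called (28 higher, 65 lower). These calls rest on the single remaining array of the group, replicate 2, whose spread was then taken from the other groups.

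After 7 days without watering, the same comparison in water-grown mycelium gave AGABI2DRAFT_136259 the largest positive log2 change (3.63 ± 1.79, adjusted p 0.997), with ratios of 3.92 and 3.34 on the arrays. The error again includes the opposed riboflavin ratios of this gene. AGABI2DRAFT_114522 followed with 2.05 ± 0.68, from ratios of 3.85 and 0.25, with the irrigated channel well above background on 1 of the 2 arrays. The largest negative changes were those of AGABI2DRAFT_121746 (-2.95 ± 1.24) and AGABI2DRAFT_123048 (-2.94 ± 1.16). Neither was well above background in the drought channel of either array. In the mean of the 2 arrays the irrigated signal was at least 7.49-fold and at least 7.68-fold higher. Replicate 2 lay below these bounds, with log2 ratios of -2.30 and -2.33. AGABI2DRAFT_189493 had the smallest p and near-equal ratios of 0.96 and 0.95 (adjusted p 0.750). AGABI2DRAFT_139997 (-0.98 ± 0.21) and AGABI2DRAFT_121457 (0.64 ± 0.14) came next, both with an adjusted p of 0.997. Limma called 0 genes, and 13 had an unadjusted p under 0.05 where chance gives 31.9. Fitted alone, without the riboflavin arrays, the water arrays gave no call on either day.

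Over both days, 4 genes had a log2 ratio above 0.5 on all 4 water arrays. They were AGABI2DRAFT_136259 (mean 3.41 ± 0.69 SD, n = 4 arrays), AGABI2DRAFT_191238 (2.04 ± 0.71), AGABI2DRAFT_195860 (1.60 ± 0.80) and CytC2 (1.44 ± 0.46), whose symbol denotes a cytochrome c, the electron carrier of the respiratory chain. A further 16 genes had a ratio below -0.5 on all 4, of which 15 belong to the set of 18. These counts were made after the values were seen. All 4 water arrays gave the same sign for 22.1% of the genes, where independent signs give 12.5%. The corresponding share for the 4 riboflavin arrays was 13.3%.

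**Figure D2:**
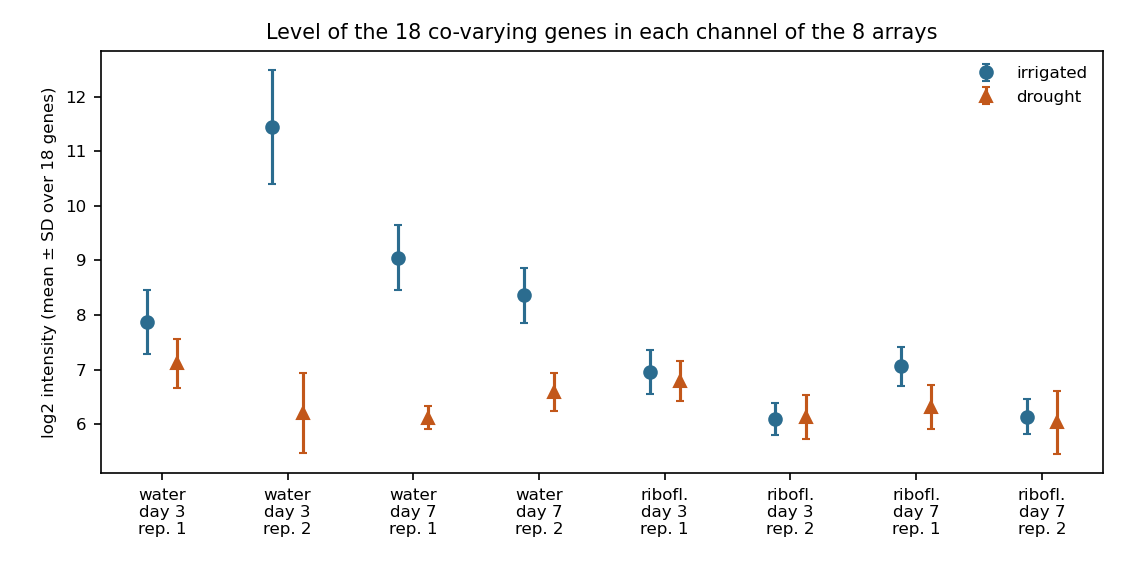
Mean log2 intensity (vertical axis, ± SD over the genes) of the 18 genes that varied together, in the irrigated (circles) and drought (triangles) channel of each of the 8 arrays (horizontal axis). Irrigated means lie at 7.87 to 11.44 on the water arrays, above drought means of 6.12 to 7.12, and at 6.10 and 6.13 on the riboflavin replicate 2 arrays.

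With riboflavin, 3 days of drought gave the largest positive log2 changes to AGABI2DRAFT_75870 (2.20 ± 0.92) and AGABI2DRAFT_75612 (2.19 ± 0.92), but the ratios of AGABI2DRAFT_75870 were near 0 on replicate 1 and 4.39 on replicate 2. The largest negative changes were those of AGABI2DRAFT_139997 (-2.14 ± 0.21, adjusted p 0.205) and AGABI2DRAFT_136259 (-1.78 ± 1.79), the latter from ratios of 1.48 and -5.04. Without replicate 2 on either day, the value of AGABI2DRAFT_136259 was 0.98. With replicate 2 turned, AGABI2DRAFT_75870 stood at -2.08, AGABI2DRAFT_139997 at 0.10 and AGABI2DRAFT_136259 at 2.76. AGABI2DRAFT_189575 (1.08 ± 0.12) and AGABI2DRAFT_75272 (0.81 ± 0.10) were positive on both arrays, each with an adjusted p of 0.205 by limma. With replicate 2 turned they were -0.091 and 0.12. The irrigated channel of AGABI2DRAFT_75272 was well above background on 1 of them. No gene was called by limma, and 48 had an unadjusted p under 0.05 (37 higher, 11 lower) against 31.9 by chance. With the riboflavin arrays fitted alone, 2 genes were called, AGABI2DRAFT_139997 and AGABI2DRAFT_135951 (the latter named after its values were seen). That fit of 4 arrays kept the dye term, which equals replicate number. Replicate deviations correlated at 0.92 between the riboflavin days, so the opposition they share went into this term and not into the error. The errors behind these 2 calls may therefore be too small. With all 10413 probes tested 3 were called (AGABI2DRAFT_139997, AGABI2DRAFT_189575 and AGABI2DRAFT_75272).

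On day 7 with riboflavin, AGABI2DRAFT_205009 had the largest positive log2 change (2.37 ± 0.37, adjusted p 0.353), with ratios of 2.86 and 1.89. AGABI2DRAFT_194064 had 1.62 ± 0.33, with the irrigated channel well above background on 1 array. AGABI2DRAFT_139997 had the largest negative change (-2.78 ± 0.21, adjusted p 0.0737), followed by AGABI2DRAFT_133899 (-2.34 ± 0.52). With replicate 2 turned, these 4 values were 0.48 (AGABI2DRAFT_205009), 0.34 (AGABI2DRAFT_194064), 0.11 (AGABI2DRAFT_139997) and -0.86 (AGABI2DRAFT_133899). AGABI2DRAFT_150982, with 0.69 ± 0.10 and an adjusted p of 0.353 by limma, was among the 3 smallest p-values (-0.075 if turned). Limma called 0 genes and 27 had an unadjusted p under 0.05 against 31.9 by chance. With the riboflavin arrays fitted alone, 6 genes were called (2 higher, 4 lower), with the same limit from the dye term as on day 3. With all 10413 probes tested 1 was called, AGABI2DRAFT_139997. Leaving out either array of water day 3 also gave 1 call, the same gene.

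The part of the drought response shared by the 4 groups held 1 called gene. AGABI2DRAFT_139997 fell by 1.64 on the log2 scale (SE 0.106, adjusted p 0.0363, limma), and its ratio was below 0 on 8 of 8 arrays. Its ratios were -0.54, -0.80, -0.30 and -1.66 on the water arrays and -1.63, -2.65, -2.26 and -3.30 on the riboflavin arrays. Its function is not given in the tables used here. The adjusted p was 0.0765 without the dye term, 0.0880 with median centring (which put 1 of its ratios, on water day 3 replicate 2, at 0.06), 0.104 with the processed signals, 0.155 with the deposited ratios, 0.213 with an intensity trend and robust fit and 0.593 with each dye pair counted as 1 value. Replicate deviations correlated at 0.92 between the riboflavin days, and with supplement and replicate number as a random block (correlation 0.544) its adjusted p was 0.316. With the riboflavin replicate 2 arrays turned its mean was -0.36 (adjusted p 0.865), and without them -1.59 (adjusted p 0.216). The call was also lost when any 1 of the 4 riboflavin arrays or the 2 water day 7 arrays was left out, with an adjusted p of up to 0.554.

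AGABI2DRAFT_205009 (1.16 ± 0.19, positive on 7 of 8 arrays, adjusted p 0.203) and AGABI2DRAFT_191238 (1.13 ± 0.68) had the largest positive means over the 4 groups. With riboflavin replicate 2 turned these were 0.21 and 2.39. AGABI2DRAFT_121746 (-1.78 ± 0.62) and AGABI2DRAFT_194860 (-1.73 ± 0.58) had the largest negative ones, and neither passed the test (adjusted p 0.549 each). The drought channel was well above background on 3 of 8 arrays for AGABI2DRAFT_121746 and 6 of 8 for AGABI2DRAFT_194860, and the irrigated channel on 6 of 8 for both, so these sizes and places are not exact. In all, 56 genes had an unadjusted p under 0.05 (27 higher and 29 lower) against 31.9 by chance. Without water day 3 replicate 1, 78 genes were called (25 higher, 53 lower), again with replicate 2 as the single array of that group. Ratios of 20 genes had the same sign on all 8 arrays, 7 above and 13 below 0, where independent signs give 4.98. Signs are not independent, since riboflavin arrays of the 2 days correlated at 0.68 and 0.88. Members of the set of 18, such as AGABI2DRAFT_194860, are also counted singly. The number for independent signs is therefore no test of this count.

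**Figure D3:**
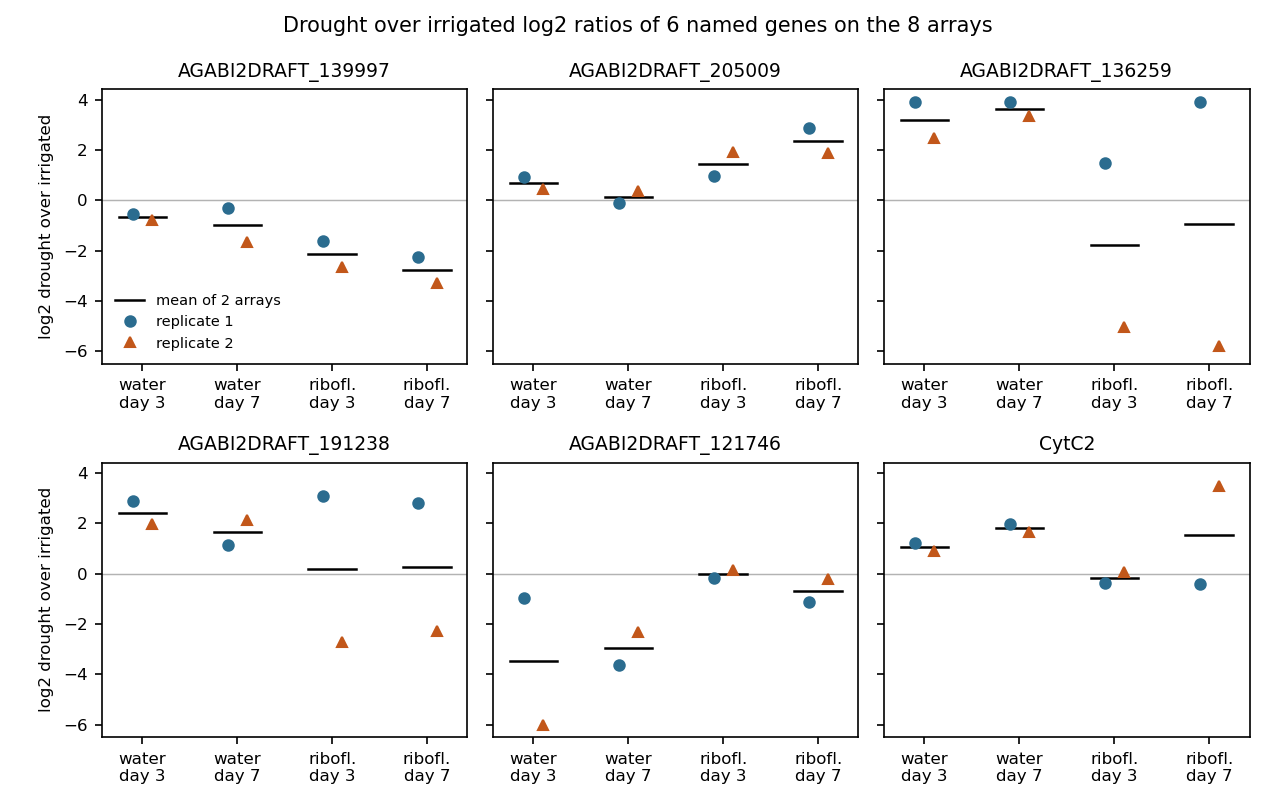
Log2 drought-over-irrigated ratios (vertical axis) of 6 named genes on each array of the 4 groups (horizontal axis); circles are replicate 1, triangles replicate 2 and bars the mean of the 2 arrays. AGABI2DRAFT_139997 lies below 0 on 8 of 8 arrays, while AGABI2DRAFT_136259 lies at 2.46 to 3.92 on the water arrays and at -5.04 and -5.79 on the riboflavin replicate 2 arrays.

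Whether riboflavin changed the response to drought was tested as the difference between the riboflavin and the water response on each day. On day 3 the largest negative differences were those of AGABI2DRAFT_136259 (-4.96 ± 2.54 log2 units) and AGABI2DRAFT_195860 (-3.33 ± 2.30). Their riboflavin ratios were opposed, at 1.48 and -5.04 for AGABI2DRAFT_136259 and 1.85 and -5.40 for AGABI2DRAFT_195860. With replicate 2 turned the differences were -0.43 and 1.42, and without it -2.20 and -0.36. The largest positive ones were those of AGABI2DRAFT_121746 (3.47 ± 1.75, 2.40 if turned) and AGABI2DRAFT_146400 (3.26 ± 1.73, 2.26 if turned). Both were low under drought with water and near 0 with riboflavin. On riboflavin replicate 2 neither channel of these 2 genes was well above background, so the sizes and order are not exact. The same holds for AGABI2DRAFT_195860 (irrigated channel on both water arrays) and for AGABI2DRAFT_200290 and AGABI2DRAFT_196048 below. AGABI2DRAFT_139997 had the smallest p (-1.46 ± 0.30), followed by AGABI2DRAFT_200290 (1.61 ± 0.34) and AGABI2DRAFT_196048 (-0.90 ± 0.20), all with an adjusted p of 0.653. Turned, these 3 were 0.78, 1.42 and -0.45. No gene was called by limma, and 22 had an unadjusted p under 0.05 against 31.9 by chance. Genes were called at an adjusted p under 0.05 when water day 3 replicate 1 was left out, but these calls rest on the single remaining array of that group.

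On day 7, AGABI2DRAFT_136259 (-4.58 ± 2.54) and AGABI2DRAFT_195860 (-2.18 ± 2.30) again had the largest negative differences, and AGABI2DRAFT_187811 (2.52 ± 1.95, but -0.33 without water day 7 replicate 2) and AGABI2DRAFT_123048 (2.40 ± 1.64) the largest positive ones. The riboflavin ratios were 3.91 and -5.79 for AGABI2DRAFT_136259 and 3.79 and -4.88 for AGABI2DRAFT_195860. With replicate 2 turned, the differences were 0.71 for AGABI2DRAFT_136259, 2.05 for AGABI2DRAFT_195860, -1.11 for AGABI2DRAFT_187811 and 1.56 for AGABI2DRAFT_123048. The drought channel of AGABI2DRAFT_123048 was well above background on none of the 4 arrays of day 7 and its irrigated channel not on riboflavin replicate 2, so neither its size nor its place is exact. That of AGABI2DRAFT_195860 is limited by the irrigated channel of both water arrays. The smallest p-values were those of AGABI2DRAFT_139997 (-1.80 ± 0.30), AGABI2DRAFT_183881 (-1.26 ± 0.21) and AGABI2DRAFT_121457 (-0.94 ± 0.20), with an adjusted p of 0.961 each (turned, 1.09, -0.37 and -0.87). Averaged over the days, AGABI2DRAFT_136259 had a difference of -4.77 ± 1.79 and AGABI2DRAFT_195860 one of -2.76 ± 1.62 (turned, 0.14 and 1.73). AGABI2DRAFT_121746 had 2.87 ± 1.24 and AGABI2DRAFT_123048 2.75 ± 1.16 (turned, 1.98 and 1.87), with the same limit. AGABI2DRAFT_139997 (-1.63 ± 0.21), AGABI2DRAFT_183881 (-0.99 ± 0.15) and AGABI2DRAFT_150982 (0.58 ± 0.10) had the smallest p-values, with an adjusted p of 0.668 each (turned, 0.93, -0.27 and 0.11). Limma called 0 genes on day 7 and 0 in the mean of days, with 22 and 32 at an unadjusted p under 0.05. For the mean of days, leaving out water day 3 replicate 1 gave 73 calls (51 higher, 22 lower). The difference of AGABI2DRAFT_195860 turned positive when both riboflavin replicate 2 arrays were left out (1.503 on day 7 and 0.57 in the mean of days), and on day 7 also without water replicate 2 (0.34) or riboflavin replicate 2 (0.51) of that day.

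Drought responses on day 7 and day 3 were set against each other within each supplement. With water, AGABI2DRAFT_64309 (2.39 ± 2.07, but -0.11 without day 7 replicate 2) and AGABI2DRAFT_114522 (1.86 ± 0.96) had the largest positive differences. Ratios of AGABI2DRAFT_114522 were 0.14 and 0.24 on day 3 and 3.85 and 0.25 on day 7, so replicate 1 of day 7 carried its difference. Its irrigated channel was not well above background on day 7 replicate 2. AGABI2DRAFT_195164 (-2.002 ± 1.13) and AGABI2DRAFT_182197 (-1.78 ± 0.91) had the largest negative ones, both from day 3 replicate 2 alone, where the ratio of AGABI2DRAFT_182197 was 3.34. Channels of these 2 genes and of AGABI2DRAFT_151612 were in part near background, as were those of AGABI2DRAFT_195960 and AGABI2DRAFT_43497 with riboflavin, so their sizes are not exact. AGABI2DRAFT_189493 (1.04 ± 0.18), AGABI2DRAFT_120986 (-0.95 ± 0.18) and AGABI2DRAFT_151612 (0.87 ± 0.22) had the smallest p-values (adjusted p 0.997). With riboflavin, AGABI2DRAFT_186299 (1.92 ± 1.68) and CytC2 (1.70 ± 1.17, but -0.26 without day 7 replicate 2) lay highest, and AGABI2DRAFT_144976 (-1.80 ± 0.99) and AGABI2DRAFT_195960 (-1.68 ± 0.65) lowest. With replicate 2 turned these 4 were 0.12, -1.70, -0.28 and 1.21. AGABI2DRAFT_189575 (-1.01 ± 0.18) had the smallest p there. The next 2 were those of AGABI2DRAFT_194141 (0.76 ± 0.22) and AGABI2DRAFT_43497 (0.72 ± 0.21), and all 3 had an adjusted p of 0.999 (turned, -0.10, 0.27 and -0.071). No gene was called by limma in either supplement, and 18 (water) and 12 (riboflavin) had an unadjusted p under 0.05. Without water day 3 replicate 1, 77 genes were called in the water comparison (53 higher and 24 lower on day 7).

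In irrigated mycelium, the supplement itself was compared through the separate channels. On day 3, AGABI2DRAFT_136259 (5.17 ± 1.42) and AGABI2DRAFT_195860 (4.09 ± 1.28) had the largest positive log2 changes of riboflavin over water. Their irrigated log2 intensities on the riboflavin arrays were 11.02 and 14.45 (AGABI2DRAFT_136259) and 8.37 and 11.997 (AGABI2DRAFT_195860), the higher value on replicate 2 each time. With the channels of the riboflavin replicate 2 arrays exchanged the changes were 2.90 and 1.72, and without those arrays 3.71 and 2.61. AGABI2DRAFT_195860 was not well above background in irrigated mycelium with water, and its mean over the 2 riboflavin arrays as labelled was at least 17.1-fold higher. Replicate 1 alone lay well below that bound, at 8.37 against 6.03 and 6.15 on the water arrays. AGABI2DRAFT_121746 (-3.80 ± 1.14) and AGABI2DRAFT_120132 (-3.75 ± 1.15) had the largest negative ones (-3.27 and -3.25 if exchanged). Irrigated intensities of AGABI2DRAFT_121746 were 8.54 and 12.34 on the water arrays and 7.33 and 5.95 with riboflavin, and those of AGABI2DRAFT_120132 8.29 and 12.48 against 7.29 and 5.97. Replicate 2 thus carried most of both changes, and its riboflavin values were not well above background. All 4 had an adjusted p of 0.272. AGABI2DRAFT_200290 (-1.29 ± 0.24) and AGABI2DRAFT_195355 (3.38 ± 0.65) had the smallest p-values (adjusted p 0.204), followed by AGABI2DRAFT_114663 (-3.57 ± 0.96). If exchanged, these 3 were -1.20, 2.08 and -3.10. AGABI2DRAFT_200290 was not well above background in irrigated mycelium with riboflavin, and was at least 2.45-fold lower there in the mean of the 2 arrays. No gene was called by limma, but 85 of 634 had an unadjusted p under 0.05 (20 higher, 65 lower) against 31.7 by chance. As above, the chance number assumes independent genes and is no test, and the count of 85 changed widely between the alternatives. Quantile normalization of the 16 channels called 2 genes (AGABI2DRAFT_200290 and AGABI2DRAFT_195355), and leaving out water day 3 replicate 1 called 61 (3 higher, 58 lower).

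On day 7 the same pair, AGABI2DRAFT_136259 (5.13 ± 1.42, adjusted p 0.930) and AGABI2DRAFT_195860 (3.35 ± 1.28), lay highest with riboflavin. Their irrigated intensities on the riboflavin arrays were 9.98 and 14.09 (AGABI2DRAFT_136259) and 6.90 and 11.66 (AGABI2DRAFT_195860). With the channels of replicate 2 exchanged the changes were 2.48 and 1.24, and without those arrays 3.33 and 1.30. AGABI2DRAFT_195860 was again not above background with water, and its mean over the 2 riboflavin arrays as labelled was at least 10.2-fold higher. Replicate 1 alone lay well below that bound, at 6.90 against 5.74 and 6.12 on the water arrays. AGABI2DRAFT_123048 (-2.57 ± 1.21) and AGABI2DRAFT_116162 (-2.48 ± 1.17) lay lowest. On riboflavin replicate 2, at 5.98 and 6.03, neither was well above background, while replicate 1 had 7.32 and 7.13 and the water arrays 8.73 to 9.69. AGABI2DRAFT_195355 had 3.02 ± 0.65 (adjusted p 0.855) and AGABI2DRAFT_183881 0.98 ± 0.30 (adjusted p 0.930), or 1.71 and 0.54 if exchanged. Limma called 0 genes, and 17 of 634 had an unadjusted p under 0.05 against 31.7 by chance. Quantile normalization called 1 gene, AGABI2DRAFT_195355. Leaving out either array of water day 3 called 21, all lower with riboflavin.

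Of the genes that carry a symbol, those of the respiratory chain and ATP synthase were the only group with tested members. This grouping by symbol was made after the files were seen. Of 55 such genes on the array, 11 were above background on any array and 4 were tested (CytC2, SDH1, SDH2 and NdufA1). CytC2 had a mean log2 drought-over-irrigated ratio of 1.44 ± 0.46 (SD, n = 4 arrays) with water and 0.69 ± 1.87 with riboflavin, where 1 array (day 7 replicate 2) stood at 3.47. Its mean over the 4 groups did not pass the limma test (1.06 ± 0.42 SE, adjusted p 0.549). That mean includes the array at 3.47, and its value with riboflavin replicate 2 turned was not computed. NdufA1, a symbol used for a subunit of respiratory complex I, was not well above background in any irrigated channel. Its drought channel was well above background on 5 of 8 arrays, so no fold over the 4 groups is given. Its ratio was positive on 7 of 8 arrays and did not pass the test (adjusted p 0.231). SDH1 and SDH2, named for succinate dehydrogenase subunits, had mean changes of -0.52 ± 0.40 and 0.07 ± 0.09 (adjusted p 0.664 and 0.763), SDH2 with the irrigated channel well above background on 3 of 8 arrays. The ratios of SDH1 were 0.26 and 0.98 on the riboflavin replicate 1 arrays and -2.68 and -2.65 on the replicate 2 arrays, with a mean of -0.02 on the water arrays. Its negative mean change thus rests on riboflavin replicate 2, and its value with those arrays turned was not computed. Fet3, named for the multicopper oxidase of high-affinity iron uptake, was the fifth tested gene with a symbol. It was well above background in no drought channel and in the irrigated channel of 2 of 8 arrays, so no fold is given (adjusted p 0.657). None of the 4 respiratory genes and not Fet3 was called in any of the 12 comparisons. Of 7 laccase and manganese peroxidase genes, which act in lignin breakdown, 1 was above background on any array. Among 5 heat shock genes 2 were, and among 6 genes of osmosensing and histidine kinase signalling 1 was. None of these was tested.

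Mean drought responses of the groups were compared across the tested genes. Water day 3 and day 7 correlated at r = 0.73 (Spearman's rho 0.30), and riboflavin day 3 and day 7 at r = 0.54 (rho 0.42). Correlations between a water and a riboflavin group lay between -0.12 and 0.23. No gene was called in any pair of groups. At an unadjusted p under 0.05, 10 genes were higher and 3 lower under drought on both riboflavin days, where independent lists give 1.16 and 0.121. The groups share no arrays, but they share 1 estimate of the spread per gene, which can add to such overlaps. Replicate deviations also correlated at 0.92 between the riboflavin days, so these lists are not independent and the numbers for independent lists are no test of the overlap.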

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

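The tests of an exchange of RNA (single channels and ranks included) and of dye bias were chosen only after the result was seen. Groups of 2 arrays are too small for a search for single deviating arrays. For 7 of the values given for a gene in a difference between groups, both arrays of one group lay on one side of 0 and both of the other group on the opposite side. The difference itself was tested by limma and did not pass for any of them. The riboflavin-minus-water difference on day 3 was -0.90 for AGABI2DRAFT_196048 (adjusted p 0.653), and on day 7 it was -0.94 for AGABI2DRAFT_121457 (adjusted p 0.961). The difference of day 7 minus day 3 with water was 1.04 for AGABI2DRAFT_189493, -0.95 for AGABI2DRAFT_120986 and 0.66 for SDH1 (adjusted p 0.997 each). With riboflavin it was 0.76 for AGABI2DRAFT_194141 and 0.72 for AGABI2DRAFT_43497 (adjusted p 0.999 each). Outside the comparisons they are named for, 6 of the 42 named genes showed the same pattern, such as AGABI2DRAFT_150982 (riboflavin minus water, day 3, 0.49) and AGABI2DRAFT_189575 (day 7 minus day 3, water, -0.58), with no adjusted p under 0.653. Independent signs put 12.5% of genes into such a pattern. The observed shares over all tested genes were 6.77% and 8.63% for the riboflavin differences on days 3 and 7, and 11.4% and 4.87% for the day differences with water and riboflavin.

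For the opposed riboflavin arrays, gene-specific dye bias is argued against for 33 genes opposed on both riboflavin days. Their dye component in the water arrays was only 0.0182 times that in the riboflavin arrays (95% bootstrap interval over genes -0.0141 to 0.0654). The interval measures the spread over these genes, which share the same arrays and are not independent, and not the spread between arrays. The opposition does not rest on the brightest genes alone, since outside the brightest 10% of tested genes the arrays still correlated at -0.307 on day 3 and -0.474 on day 7. The dimmer genes were normalized together with the bright ones, so this test cannot decide whether the normalization passed a distortion on to them. With median centring in place of loess, the arrays correlated across all tested genes at -0.42 on day 3 and -0.46 on day 7. Whether drought and irrigated RNA were exchanged on both replicate 2 arrays could not be decided. With their sign turned the arrays correlated at r = 0.120 and 0.113 with the mean water response (0.329 for replicate 1), above the 0.1 set for an exchange, but by ranks at only 0.00934 and 0.0239 (0.260 for replicate 1), and 4 genes (AGABI2DRAFT_139997, AGABI2DRAFT_117817, AGABI2DRAFT_194933 and AGABI2DRAFT_205009) lay beyond 0.5 in one direction on all 4 riboflavin arrays as labelled, where at most 1 was set. Beside these 4, the 33 opposed genes above, also beyond 0.5 on all 4 riboflavin arrays, had 1 sign within each day only if turned. They are the opposition to be explained, so their number does not decide its cause. A difference between the replicate cultures was not tested. For the set of 18 genes described below, the replicates did differ in a way that an exchange would leave in place. All 18 were well above background in the irrigated channel of both riboflavin replicate 1 arrays, and at most 3 in any channel of replicate 2.

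Single channels, compared between a replicate 1 and a replicate 2 array across genes, did not decide it. Before correlating, each gene's mean over all channels of all arrays was subtracted. The correlations therefore compare deviations from that mean, not plain intensities. Negative values mean opposed deviations, and the level of each range also depends on the channels of the other groups. With riboflavin, Cy3 channels (both drought after an exchange) correlated at 0.43 to 0.70 and Cy5 channels (both irrigated after an exchange) at -0.022 to 0.27. As labelled, the riboflavin drought channels correlated at -0.14 to 0.10 and the irrigated ones at -0.42 to -0.20. With water, drought channels correlated at -0.16 to 0.014 and irrigated channels at 0.50 to 0.74, so an exchange brings neither pair to the range of its water counterpart.

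The call of AGABI2DRAFT_139997 in the mean drought response was set against chance. Drought and irrigated were exchanged at random on single arrays, and 10 of 100 orientations, the real one included, called at least 1 gene, so chance is not excluded for a count of this size. The highest of the other orientations, with drought and irrigated exchanged on replicate 2 of both water days, called 56 genes. In that orientation all 4 water arrays are treated as carrying drought RNA in the same dye. The dye term then rests on the riboflavin pairs alone and enters the mean drought response. The real design is balanced for dye in every group, so the count of 56 cannot be set against it directly. Every orientation that exchanges 1 array of a group lacks this balance, which limits the comparison with all 100. For the riboflavin-minus-water difference in the mean of days, the real split called 0 genes. All 34 splits of the arrays into 4 and 4 that could be fitted call at least that many by definition, so they decide nothing about it. The highest other split called 3 (replicate 1 of water with replicate 2 of riboflavin against the rest), and 1 split equals the dye orientation and could not be fitted.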

How the results depend on the processing

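The sign turn (an exchange of channels for irrigated mycelium), the omission of both riboflavin replicate 2 arrays and the random block were chosen only after the data were examined. Where a count or sign changed, the cause was not tested, unless stated. Counts of 0 stayed at 0 under the alternatives not named here. Aquantile changes no log2 ratio, there is 1 probe per gene so averaging probes changes nothing, and the gene list alternatives were not run because no list fixed beforehand had a tested gene. The 1 call in the mean drought response became 4 without the filter on dim probes. It became 0 with processed signals, median centring, no replicate block (no dye term), intensity trend with robust fit, the deposited log2 ratios, averaged dye pairs, the sign turn, both riboflavin replicate 2 arrays left out, and the random block of supplement and replicate number (consensus correlation 0.544). The adjusted p of AGABI2DRAFT_139997 ranged from 0.00326 to 0.865 over these settings. Without the filter, 3 genes were called for riboflavin day 3 and 1 for day 7, with the stricter filter of 89 probes 1 for day 7, and with each supplement alone 2 and 6. In the fit of riboflavin alone, the dye term takes up the opposition shared by both days, so the counts of 2 and 6 may be too high. In irrigated mycelium, quantile normalization called 2 genes on day 3 and 1 on day 7, and no background correction called 1 on day 3. With single arrays left out, calls ranged from 0 to 93 (drought, water day 3), 0 to 78 (mean drought), 0 to 80 and 0 to 73 (riboflavin minus water, day 3 and mean of days), 0 to 77 (day difference, water), 0 to 61 and 0 to 21 (irrigated, day 3 and day 7) and 0 to 1 (drought, riboflavin day 7). The upper ends came without water day 3 replicate 1 (for irrigated day 7 and for drought on riboflavin day 7, either array of that group). In comparisons that use water day 3, this leaves the group 1 array assumed to vary like the others. Irrigated day 7 and drought on riboflavin day 7 do not use that group, so there the shared estimate of the spread changed. Numbered replicates did not deviate together: deviations correlated at -0.15 to 0.06 between groups, except 0.92 between the riboflavin days. Processed signals moved the median gene of water day 3 to -0.22 from -0.03 (log2).

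Turning the sign reversed, by construction, values that rest on the riboflavin replicate 2 arrays. On riboflavin day 3 AGABI2DRAFT_75870 became -2.08, AGABI2DRAFT_75612 -2.09, AGABI2DRAFT_139997 0.10, AGABI2DRAFT_136259 2.76 and AGABI2DRAFT_189575 -0.091. On day 7 AGABI2DRAFT_139997 became 0.11 and AGABI2DRAFT_150982 -0.075. In the riboflavin-minus-water differences AGABI2DRAFT_195860 became 1.42, 2.05 and 1.73 (day 3, day 7, mean) and AGABI2DRAFT_139997 0.78, 1.09 and 0.93. AGABI2DRAFT_136259 became 0.71 and 0.14 (day 7, mean) and AGABI2DRAFT_187811 -1.11 (day 7). In the riboflavin day difference CytC2 became -1.70, AGABI2DRAFT_195960 1.21 and AGABI2DRAFT_43497 -0.071. Without both riboflavin replicate 2 arrays, AGABI2DRAFT_136259 became 0.98 (drought, day 3), AGABI2DRAFT_195860 1.503 and 0.57 (differences, day 7 and mean) and CytC2 -0.0094. With single arrays left out, AGABI2DRAFT_187811 ranged from -0.33 to 5.37 and AGABI2DRAFT_195860 from -4.87 to 0.51 (differences, day 7), AGABI2DRAFT_64309 from -0.11 to 4.90 (water day difference) and CytC2 from -0.26 to 3.65 (riboflavin day difference). Values under the alternatives were tallied for genes named in a comparison by largest change, smallest p or call. Of these, 1413 kept direction and side of the threshold, 37 passed it newly, 15 no longer passed it and 28 changed sign. Genes named only for their symbol, for a shared sign or for a call under an alternative were not in this tally.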

Other observations

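A set of 18 genes varied almost as 1 unit across the arrays. They were found by a correlation above 0.97 with AGABI2DRAFT_121746 over the 8 arrays, and so were chosen after their values were seen. Their log2 drought-over-irrigated ratios averaged -0.76, -5.23, -2.93 and -1.77 on the 4 water arrays (day 3 replicates 1 and 2, day 7 replicates 1 and 2). The SD over the genes was 0.19, 0.62, 0.58 and 0.42. In the drought channel of these arrays 17, 14, 3 and 1 of the 18 were well above background. On day 7 the ratios of most members thus rest on a drought channel near background, and their sizes are not exact. In the irrigated channel all 18 were well above background on each water array and on both riboflavin replicate 1 arrays. On the riboflavin replicate 2 arrays they were above background for 1 gene of 18 in the irrigated channel of each day. In the drought channel of those arrays they were so for 3 genes on day 3 and 1 on day 7. An exchange of the 2 RNAs would leave this absence from both channels in place. None of the 18 has a symbol. Of the 16 genes below -0.5 on all 4 water arrays, 15 belong to this set.

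A hypothesis, written before its test was run, was that the set forms a gene cluster on a chromosome. In the order of genes in the reference assembly, 0 pairs of its members lay within 5 gene positions of each other, and random sets of 18 tested genes had a median of 0 and a 95th percentile of 1, which argues against one cluster. Neighbouring tested genes in general did not respond alike either: over 51 adjacent pairs the median correlation of the 8 ratios was -0.0148, where random pairs gave 0.0281 with a 95th percentile of 0.177 (one-sided permutation p = 0.695). What the 18 genes share stays open, since the tables used here give them no function.

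A second set of genes, also chosen after their values were seen, was opposed between the riboflavin arrays. AGABI2DRAFT_195355, AGABI2DRAFT_195860, AGABI2DRAFT_136259 and AGABI2DRAFT_191238 had positive ratios on every water array and on both riboflavin replicate 1 arrays. On both riboflavin replicate 2 arrays their ratios lay between -5.79 and -2.28.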
